A study of Homo sapiens with 8 samples.

How the data were processed

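RNA from 8 cultures of IMR-90 cells, a line of human lung fibroblasts, was measured on 8 arrays of 1 Illumina BeadChip. The cells were either the parental line, which has a limited life span, or a derivative immortalized with hTERT, the catalytic protein of telomerase. Each of the 2 cell types had received an empty vector, wild-type hTER, or 1 of the 2 mutant forms 47A and AU5. hTER is the RNA that telomerase copies into telomere repeats. Each of the 4 constructs was on 1 array per cell type, so no construct had a second array in the same cells. The labels give no replicate numbers and do not say that the cultures were grown independently.

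Total RNA was amplified to labelled cRNA, per the labels. The main values were the mean bead intensity of each of 22184 probes, deposited without normalization. The detection p-value of each probe was deposited beside it, per the file headers, and ranks the probe among the negative controls of the array. Its steps correspond to 708 negative controls. GenomeStudio 2010.2, Partek and RMA are named in the submitters' processing notes, with no role stated for the last 2 of them. The authors' processed value table was deposited on a log2 scale whose centring no label states. For 99.0% of 15859 matched symbols its values lay within 0.001 of the log2 of the mean signal over the symbol's probes, so these values were not normalized between arrays. Its 18181 entries are named by symbol, and the column medians were 6.43 for AU5 and 6.51 for 47A in hTERT cells, and 6.65 to 6.89 on the other 6 arrays. Scale, centring and direction of the table were thus settled from the values.

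Signals were corrected for background by normexp with negative controls inferred from the detection p-values, quantile normalized and put on the log2 scale with an offset of 16, by the neqc function of limma 3.58.1 in R 4.3.3 with statmod 1.5.0. A probe entered the tests when its detection p-value was under 0.05 on at least 2 of the 8 arrays. Symbols in the deposited table can be old. Of the 22184 probes, 17519 carried a current symbol, 3398 were renamed through a synonym and 333 through a gene identifier. A further 172 matched several genes, 732 matched none and 30 carried a number in place of a symbol, and these kept the name in the file or went unnamed. After the filter 13859 probes with a gene were left. A gene was represented by its probe with the highest mean log2 intensity over all 8 arrays, which gave 12304 genes. Among 262 genes called in hTERT cells that had several probes, all probes went in 1 direction for 80.2%. No coordinates are given, because no label names a genome build.

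The whole design was fixed before the data were examined, except for the comparison of hTERT with parental cells under control hTER and the scaling on reference genes, which were added after seeing the data. 47A and AU5 together formed the mutant class and vector and wild-type hTER the control class. The 4 combinations of class and cell type, with 2 arrays each, were fitted together with lmFit and eBayes of limma, which left 4 residual degrees of freedom. This fit gave 4 contrasts: mutant against control in hTERT cells, mutant against control in parental cells, the interaction of mutant hTER with hTERT, and hTERT against parental cells with mutant hTER. The added contrast came from the same fit. hTERT against parental cells over all constructs was fitted with construct as a fixed term, with 3 residual degrees of freedom. The p-values were adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. In the class fit they measure the spread between the 2 constructs of a class. In the last fit they measure how the difference between hTERT and parental cells varies from construct to construct. Neither is a spread between cultures, because nothing in the labels says that arrays come from separate cultures of the same construct.

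Genes were named by a rule. For each contrast it takes up to 12 of the highest and up to 12 of the lowest log2 fold changes among genes past the threshold whose arrays did not overlap between the 2 sides. Where fewer than 6 passed in a direction it fills to 6 with the largest changes without overlap, given as values that did not pass. TERT, TERC and DKC1, and up to 4 members of each gene list by size of change, were also named. Of those members 1 is not reported here. For single constructs, up to 8 genes per direction were taken. A gene not detected on every array of a side has only a bound there. Such a fold is the mean of the brighter side over the lowest detected level of the dimmer arrays, or the dim probe's own level if that was higher, and is written "at least".

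The 23 gene lists, with 523 members in all, were p53 targets, DNA damage signalling and repair, shelterin and telomerase, apoptosis effectors and regulators, mitosis and G2/M, DNA replication and S phase, canonical histones, senescence and inflammatory secretion, interferon response, unfolded protein and ATF4 response, heat shock response, NRF2 and oxidative stress, extracellular matrix, contractile and TGF-beta genes, cholesterol synthesis, hypoxia and glycolysis, serum and immediate early genes, ribosomal proteins, reference genes, and markers of epithelial, endothelial, blood and virus packaging cells. They were tested with camera of limma at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the 23 lists of a contrast. The same lists were tested with an estimated correlation and with fry. The test with an estimated correlation can raise p even where the estimate is below the preset value. For the shelterin and telomerase list in hTERT cells the estimate was -0.022, and the camera p went from 0.022 to 0.069. A call lost there is thus by itself no measure of correlation within the list. For the 6 lists called in hTERT cells the estimates ran from 0.14 (matrix) to 0.67 (mitosis). These lie above the preset value, so the p-values at the preset correlation may be too small. fry tests whether the genes of a list move from 0 on balance in 1 direction and compares them with no other genes. Single arrays were described without a test, as the number of genes at least 1.5-fold from both control arrays of the same cells in 1 direction. List medians of single arrays were placed among 10000 random lists of the same size, matched on mean expression. Genes of a random list need not move together as genes of a real list can, so the percentiles describe and do not test.

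The alternatives were quantile normalization without background correction, normexp with median centring, the authors' value table, no filter and a filter at a detection p-value under 0.01 on all 8 arrays, the mean of a gene's probes, a trended and robust variance, construct as a fixed or random block, only the compared arrays, and leaving out each array in turn. When an array was left out, the lone array of its class was assumed to vary like the other classes. Median centring of the gene lists was also added after seeing the data.

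The procedure was tested on simulated data, for each comparison with 12304 genes of which 200 were changed, 50 at each of 4 fold sizes. For mutant against control hTER it recovered 20% of the genes changed 1.5-fold in hTERT cells and 12% in parental cells, 80% and 72% of those changed 2-fold, and 100% of those changed 4-fold in both. For the interaction it recovered 26% of the genes changed 2-fold and 100% of those changed 4-fold. False calls numbered 10 in hTERT cells, 5 in parental cells and 6 for the interaction. For hTERT against parental cells the share recovered at 2-fold was 82% with mutant hTER, 98% over all constructs and 70% with control hTER. Each simulated gene had 1 spread for all arrays. In the data 8664 genes passed in hTERT cells, where 2627 genes lay at least 1.5-fold apart between 47A and AU5. Between wild-type hTER and vector 138 did. The simulated shares therefore need not hold for contrasts with the hTERT mutant arrays. The simulation over all constructs also gave each gene the same cell-type difference in every construct, which the data did not have. The number of arrays limits the precision of every value, and the median standard error of a log2 fold change was 0.18 in the class fit, 0.25 for the interaction and 0.28 over all constructs.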

Results

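Gene expression was profiled in IMR-90 lung fibroblasts that carried an empty vector, wild-type hTER or the mutant telomerase RNAs 47A or AU5. Parental cells and cells immortalized with hTERT were each represented by 4 arrays, 1 per construct. The probe for TERT itself was not detected on any of the 8 arrays (detection p of 0.110 or higher), so the presence of hTERT was not checked by these data, and TERC, the gene for hTER, was not measured. DKC1, which encodes the telomerase component dyskerin, did not pass for mutant against control hTER in hTERT cells (log2 difference 0.09, adjusted p = 0.61).

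The 2 hTERT arrays with mutant hTER stood apart from the other 6. In hTERT cells 48.2% of probes were detected with 47A and 45.7% with AU5, against 56.7% to 58.5% on the other arrays. The 75th percentile of the unnormalized signal was 171.1 and 149.7 on these 2 arrays and 279.3 to 350.7 on the others. Normalized values correlated at r = 0.975 across genes between the 2 hTERT mutant arrays. The 15 pairs of other arrays had r of 0.974 to 0.996, and the 12 pairs with 1 hTERT mutant array had r of 0.751 to 0.841, where genes are not independent replicates. The first principal component held 86.2% of the variance and separated these 2 arrays from the rest. The median number of beads per probe was 42 or 43 on every array.

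**Figure D1:**
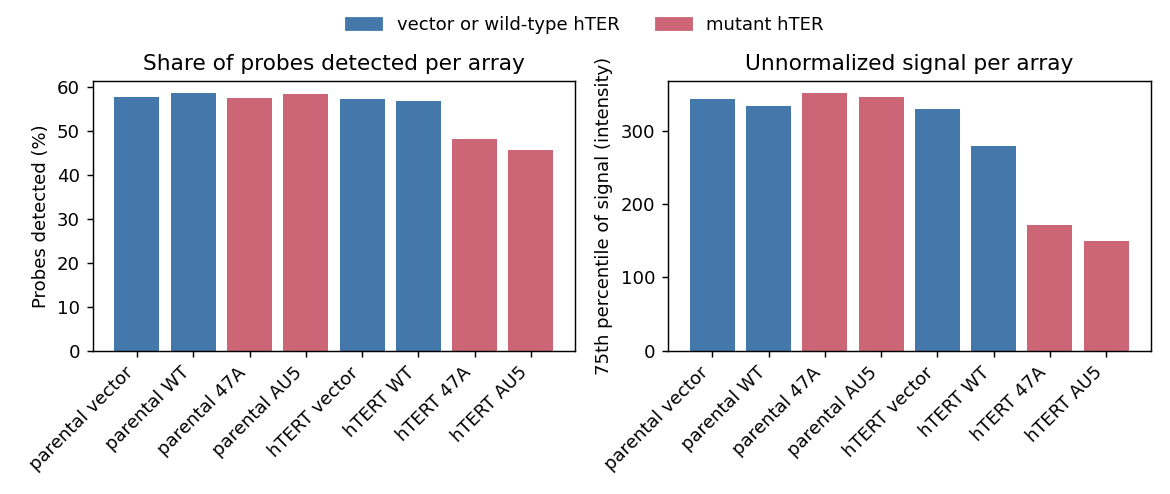
Share of probes detected (left, percent) and 75th percentile of the unnormalized signal (right, intensity) on each of the 8 arrays, 1 bar per array, with mutant hTER in red and vector or wild-type hTER in blue. The hTERT arrays with 47A and AU5 had 48.2% and 45.7% of probes detected and a 75th percentile of 171.1 and 149.7, below the other 6 arrays.

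Mutant against control hTER in hTERT cells asks how 47A and AU5 alter expression where the telomerase protein is supplied. As lists, genes of the matrix and of mitosis fell and genes of the ATF4 stress response rose in camera with a preset correlation, but 0 lists passed with an estimated correlation (adjusted p = 0.708 for each of these 3). THBS1, which encodes the matrix glycoprotein thrombospondin-1, was 66.1-fold lower with mutant hTER (log2 difference -6.05, SE 0.26, adjusted p = 1.4e-06, 2 arrays against 2). COL3A1, a fibrillar collagen, was 47.4-fold lower. PDGFRA, the receptor for platelet-derived growth factor on fibroblasts, was at least 47.5-fold lower. MMP3, the matrix protease stromelysin-1, was 40.3-fold higher (log2 difference 5.33, SE 0.20, adjusted p = 1.08e-06).

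Other genes with the largest decreases were TNFRSF11B, which encodes osteoprotegerin, at least 67.4-fold lower, and PDE5A, a phosphodiesterase for cyclic GMP, at least 72.0-fold lower. BDNF, a neurotrophin, was at least 57.4-fold lower and MAP3K20, a stress-activated kinase, 56.9-fold lower. TMEM47, a membrane protein of cell junctions, was 47.7-fold lower, and RECK, a membrane-bound inhibitor of matrix proteases, at least 31.5-fold lower. NPTX1, LRRC17 and PRRG1 were lower by at least 40.7-fold, 45.2-fold and 33.4-fold. The largest increases were in KRTAP21-2, a keratin-associated protein of hair, at least 60.4-fold, and FOLR3, a folate receptor, 51.1-fold. GCNT3, a glycosyltransferase of mucin synthesis, was 43.8-fold higher and CCL26, the chemokine eotaxin-3, 38.3-fold higher. RASD1, a small GTPase induced by glucocorticoids, was 28.2-fold higher, SPHK1, a sphingosine kinase, 27.2-fold and SLC30A3, a zinc transporter, 24.6-fold. KIF1A, a kinesin motor, ATP6V0D2, a subunit of the vacuolar proton pump, and KRTAP6-1 were higher by at least 27.0-fold, 21.8-fold and 15.5-fold. Each of these genes, and OASL, an interferon-induced gene at 22.0-fold higher, kept its direction and its call in every setting run. In total 8664 of 12304 genes passed in limma (8980 at an unadjusted p under 0.05), 4756 higher and 3908 lower, and 2569 and 2681 of them by at least 2-fold.

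The split between higher and lower depended on the scaling. The median log2 difference of all genes was 0.14 as normalized, -0.11 with median centring, -0.08 with scaling on reference genes and -0.32 in the authors' value table. Higher and lower genes numbered 2880 and 4843 with median centring, 3139 and 4785 with reference genes, and 989 and 5052 in the value table. Probes of the same gene disagreed more on these arrays: between a mutant and a control array in hTERT cells the probes differed by over 1 log2 unit for 24.2% of 395 genes on average (18.5% to 29.9% over 4 pairs). Among the other 6 arrays that share averaged 5.13% (0% to 14.4% over 15 pairs). The 3 probes for ACTB, the beta-actin gene, show the unevenness. A probe at 22178 for wild-type hTER and 22721 for vector read 20465 for 47A and 20056 for AU5, while another fell from 19888 and 18363 to 5347 and 2183.

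Matrix genes had the lowest median of the 23 lists. The list calls below are from camera with a preset correlation, and each was lost with an estimated one (adjusted p = 0.708). Of 28 measured matrix genes 24 fell and 1 rose, with a median log2 difference of -2.05 (camera, adjusted p = 1.7e-07). LUM, which encodes the collagen-binding lumican, was 43.5-fold lower and COL5A2, a fibrillar collagen chain, 28.7-fold lower. Of 21 contractile and TGF-beta genes 14 fell and 3 rose (adjusted p = 0.0044). CALD1, the actin-binding caldesmon, was 45.4-fold lower, TAGLN, a smooth muscle actin-binding protein, 12.7-fold and TPM1, a tropomyosin, 7.11-fold. The mitosis list fell, with 26 of 29 genes lower and 0 higher (adjusted p = 1.7e-07). TOP2A, the topoisomerase of mitotic chromosomes, was at least 9.71-fold lower and CCNA2, cyclin A2, at least 6.40-fold lower. In the replication list 19 of 28 genes fell and 6 rose (adjusted p = 0.0191), with TK1, thymidine kinase, 4.73-fold lower and TYMS, thymidylate synthase, 4.21-fold lower. The interferon list had 18 of 30 genes lower and 3 higher (adjusted p = 0.000795). CXCL10, an interferon-induced chemokine, was at least 6.37-fold lower, whereas OASL was higher.

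Of 24 genes of the unfolded protein and ATF4 response 18 rose and 4 fell (adjusted p = 0.0249). TRIB3, a pseudokinase induced by ATF4, was 10.6-fold higher, SESN2, a stress-induced regulator of growth signalling, 11.3-fold and SLC3A2, an amino acid transporter subunit, 5.63-fold, whereas HSP90B1, an endoplasmic reticulum chaperone, was 10.4-fold lower. All 6 of these lists kept their direction and call with every scaling run, and each had an adjusted p = 0.708 with an estimated correlation. Without the hTERT 47A array the replication list (adjusted p = 0.0559) and the ATF4 list (adjusted p = 0.0723) no longer passed. fry, which tests the lists against 0, called 18 of the 23. Markers of other cells moved with these groups: VWF, the von Willebrand factor of endothelium, was 4.77-fold higher and TEK, an endothelial receptor, 6.39-fold lower. HBA1, an alpha-globin, was 6.53-fold higher and CD68, a macrophage marker, 2.95-fold higher.

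The p53 target list did not pass as a list (adjusted p = 0.830), with 12 of 30 genes higher and 10 lower, a balance that turned to 9 and 12 with median centring, 9 and 13 with reference genes, and 5 and 13 in the value table. Its median was 0.04 while its mean was -0.15 and camera pointed down. GDF15, a cytokine induced by stress, was 16.7-fold higher (adjusted p = 2.4e-05), while ZMAT3, an RNA-binding p53 target, was 12.3-fold lower, CCNG1, cyclin G1, 12.2-fold and RRM2B, a ribonucleotide reductase subunit, at least 10.2-fold. For DNA damage signalling and repair 14 of 25 genes fell and 5 rose (adjusted p = 0.120). NBN, part of the complex that senses DNA breaks, was at least 6.70-fold lower, TOPBP1, an activator of ATR, 6.31-fold and PRKDC, the catalytic subunit of DNA-dependent protein kinase, 4.43-fold. In the shelterin and telomerase list 10 of 17 genes were higher and 1 lower (adjusted p = 0.0645), but 2 higher and 3 lower in the value table, where its mean turned negative. TERF1, which binds telomere repeats, was 3.94-fold lower, WRAP53, which guides telomerase to Cajal bodies, 3.92-fold higher and TINF2, which bridges shelterin proteins, 3.15-fold higher. For apoptosis 9 of 23 genes rose and 9 fell (adjusted p = 0.909), against 8 and 11 with median centring, 9 and 11 with reference genes and 3 and 11 in the value table. HRK, a BH3-only activator of apoptosis, was at least 14.4-fold higher, TNFRSF10A, a death receptor for TRAIL, 4.20-fold higher and APAF1, the core of the apoptosome, 7.56-fold lower.

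Serum and immediate early genes numbered 13 higher and 2 lower of 18 (adjusted p = 0.0645), but 5 and 5 in the value table, with FOSB 8.87-fold and FOS 6.46-fold higher, both subunits of the transcription factor AP-1. Of 14 canonical histones 8 rose and 1 fell (adjusted p = 0.0789), against 3 and 4 in the value table, and H2AC8 was 8.51-fold higher. In the NRF2 list 10 of 19 genes rose and 6 fell (adjusted p = 0.400; in the value table the counts were 8 and 6, with a mean below 0), with the haem oxygenase HMOX1 12.4-fold higher. Heat shock genes numbered 8 higher and 5 lower of 15 (adjusted p = 0.608), with the small heat shock protein CRYAB 9.86-fold higher. For senescence and inflammatory secretion 12 of 28 genes rose and 5 fell (adjusted p = 0.693), against 8 and 10 with median centring or reference genes and 6 and 14 in the value table. There the interstitial collagenase MMP1 was 14.2-fold higher and IGFBP5, a binding protein for insulin-like growth factors, 12.4-fold lower. For cholesterol synthesis 10 of 22 genes rose and 6 fell (adjusted p = 0.680), against 3 and 8 with median centring, 4 and 8 with reference genes and 0 and 10 in the value table. For hypoxia and glycolysis the counts were 8 and 6 of 21 (adjusted p = 0.957), and 6 and 9 with median centring, 7 and 9 with reference genes and 2 and 10 in the value table. Its median and mean were above 0 while camera pointed down.

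Of 22 ribosomal protein genes 3 rose and 5 fell (adjusted p = 0.957), against 10 and 4 with median centring, 12 and 4 with reference genes, 6 and 6 without background correction and 0 and 7 in the value table. Its median was 0.17 and its mean -0.12. Reference genes numbered 2 higher and 3 lower of 14 (adjusted p = 0.871; 0 and 8 in the value table), with a median of 0.01 and a mean of -0.24. Among 7 epithelial markers 1 rose and 2 fell (adjusted p = 0.909), with a median of 0.03 and a mean of -0.22. Among 8 endothelial markers 6 rose and 1 fell (adjusted p = 0.166), with a mean that turned negative in the value table. Blood cell markers numbered 3 higher and 0 lower of 6 (adjusted p = 0.222). Packaging cell markers numbered 3 higher and 0 lower of 5 (adjusted p = 0.222), against 0 and 2 in the value table, and NEFM, a neurofilament gene, was 3.97-fold higher. Adjusted over the list alone, 9 apoptosis genes rose and 10 fell, 18 ATF4 genes rose and 5 fell, 11 NRF2 genes rose and 6 fell, 2 ribosomal genes rose and 3 fell, and 7 endothelial markers rose and 1 fell. The other 18 lists had the counts given above when adjusted over the list alone.

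**Figure D2:**
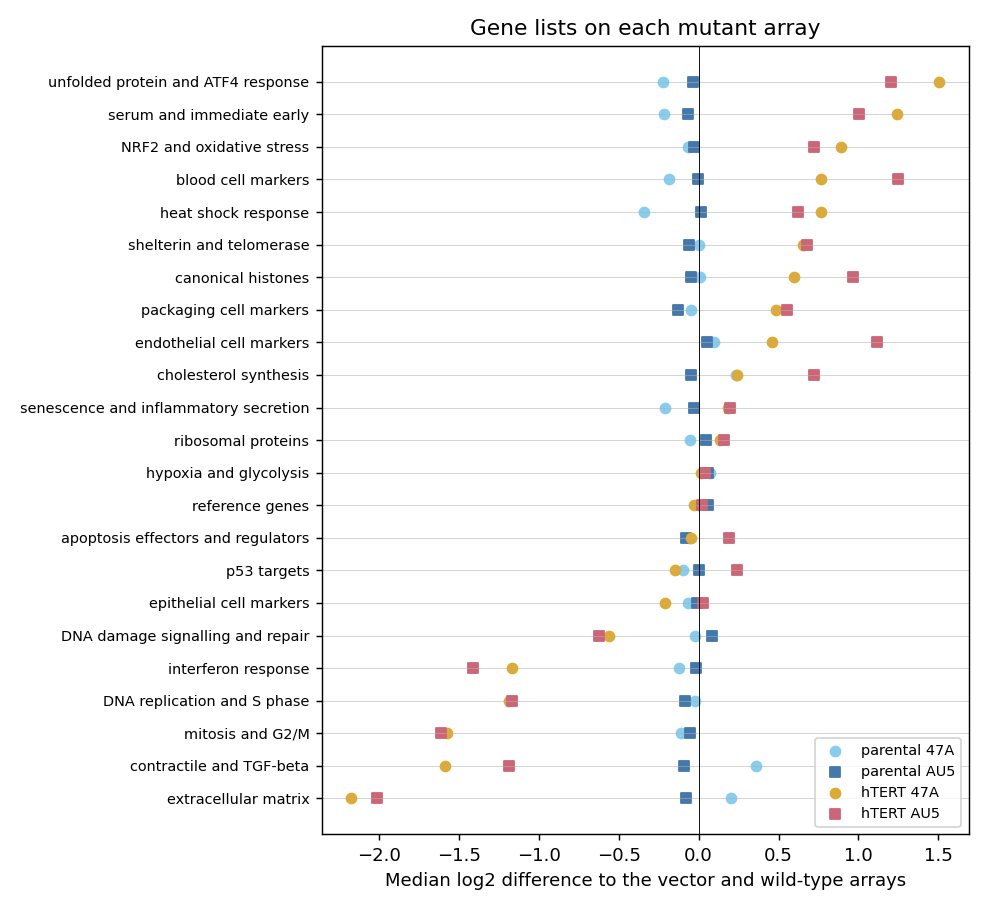
Median log2 difference of each of the 23 gene lists between a mutant array and the mean of the vector and wild-type arrays of the same cells, 1 point per array, lists ordered by the hTERT 47A array, values as normalized by quantiles. The matrix list lies at -2.17 for 47A and -2.01 for AU5 in hTERT cells and at 0.20 and -0.08 in parental cells.

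Mutant against control hTER in parental cells asks what the same RNAs do without added hTERT. Limma called 0 of 12304 genes (129 at an unadjusted p under 0.05, smallest adjusted p = 1.0). The values named below did not pass and were ranked only among genes whose mutant and control arrays did not overlap. Among these genes CYP26B1, a retinoic acid hydroxylase, was highest at a log2 difference of 1.04. ADAMTS5, an aggrecanase, was at 0.69, and FGF9 and GPC4 were at 0.66 and 0.65. ARFRP1 and HSD17B6 were at 0.63 and 0.62. On the lower side HSPA6, an inducible heat shock protein, and BIRC3, an inhibitor of apoptosis, were both at -0.99, and ROPN1B, CYP1A1, CCL26 and SPP1 at -0.81, -0.78, -0.78 and -0.66.

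As lists, 4 passed in the lower direction with 0 members past the threshold, also when adjusted over the list alone. They were the unfolded protein and ATF4 response (median -0.14, adjusted p = 0.000625), heat shock response (median -0.17, adjusted p = 0.0012), serum and immediate early genes (median -0.17, adjusted p = 0.00637) and senescence and inflammatory secretion (median -0.13, adjusted p = 0.00775). Each had an adjusted p = 0.694 with an estimated correlation, and fry called 0 lists. In each list the member farthest from 0 was DDIT3, a transcription factor of the stress response, at -0.57, HSPA6 at -0.99, FOS at -0.52 and NFKBIA, an inhibitor of NF-kappaB, at -0.64. Without the parental 47A array 0 of the 4 lists passed, without parental vector 2 passed and without parental wild-type hTER 3 passed. With median centring, with reference genes and in the value table camera called 8 lists, all lower.

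The interaction of mutant hTER with hTERT tests whether the effect of the mutants differs between the 2 cell types. It differed for 7202 genes, with 3878 higher and 3324 lower in hTERT than in parental cells. With median centring the numbers were 1864 and 4351 (median of all genes -0.17 against 0.13), with reference genes 1970 and 4410 (median -0.18), and 707 and 4475 in the value table (median -0.36). The hTERT mutant arrays, with fewer probes detected and 24.2% of genes with disagreeing probes against 5.13% among the others, enter this test too. Camera with a preset correlation called 7 lists, and 0 of them passed with an estimated one (adjusted p = 0.679, and adjusted p = 0.687 for replication). The matrix list differed by a mean of -2.42 (21 genes lower and 1 higher, adjusted p = 3.25e-07), and the mitosis list by -1.64 (23 lower and 0 higher, adjusted p = 1.37e-06). The interferon list (19 lower and 3 higher, adjusted p = 0.00312) and the contractile list (13 lower and 2 higher, adjusted p = 0.00541) also differed, as did replication (16 lower and 5 higher, adjusted p = 0.0332). The ATF4 list (18 higher and 4 lower, adjusted p = 0.0102) and serum and immediate early genes (13 higher and 1 lower, adjusted p = 0.0332) differed in the other direction, the last with 4 genes higher and 5 lower in the value table. fry called 16 lists. Adjusted over the list alone, 16 replication genes were lower and 6 higher, and the other 6 lists had the same numbers. The interferon list was lost in the value table (adjusted p = 0.0836), serum and immediate early genes without hTERT 47A (adjusted p = 0.131), and replication without hTERT wild-type (adjusted p = 0.0716), parental wild-type (adjusted p = 0.0533) or hTERT 47A (adjusted p = 0.0781). Of the 8664 genes called in hTERT cells, 7164 (82.7%) passed this test, which uses the same hTERT arrays.

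**Figure D3:**
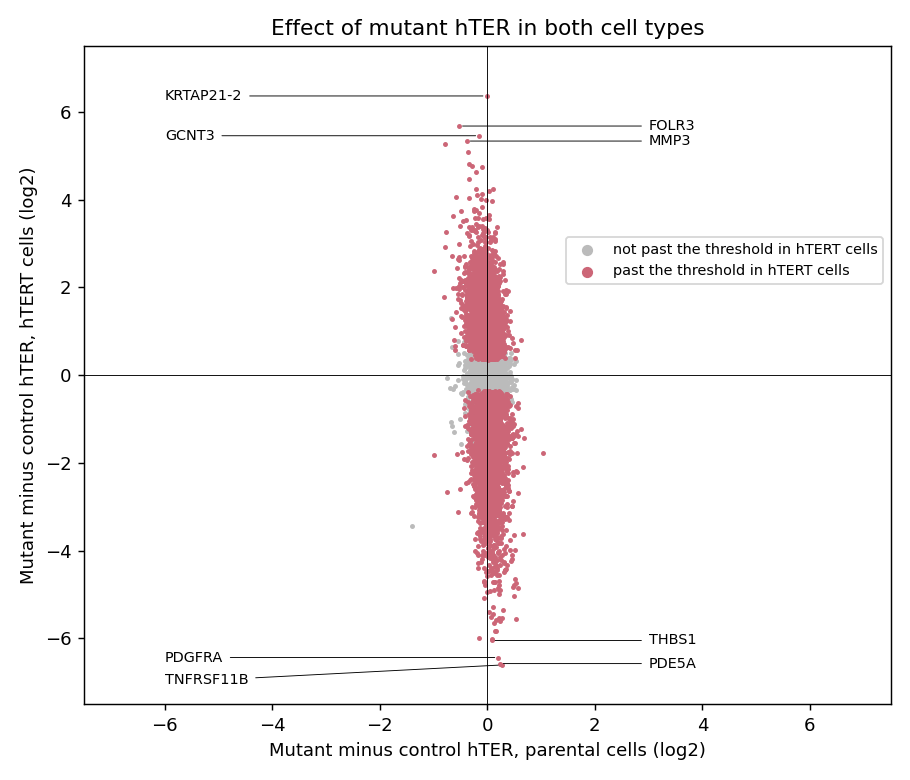
Log2 difference of mutant minus control hTER for each of 12304 genes, in parental cells (horizontal) and hTERT cells (vertical), with the 8664 genes past the threshold in hTERT cells in red. THBS1 lies at -6.05 and MMP3 at 5.33 on the vertical axis, and 0 genes passed in parental cells.

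The comparison named in the series design sets hTERT against parental cells, both with mutant hTER. The proteases MMP1 and MMP3 were 38.4-fold and 38.2-fold higher in hTERT cells. CALD1 was 76.3-fold lower (log2 difference -6.25, SE 0.49, adjusted p = 1.41e-05, 2 arrays against 2), THBS1 67.6-fold and LUM 66.5-fold. OASL was at least 41.7-fold higher. OLR1, a receptor for oxidized lipoprotein, was at least 52.7-fold lower.

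KRTAP21-2 was at least 61.5-fold higher, FOLR3 51.4-fold, GCNT3 37.5-fold, CCL26 29.5-fold, KIF1A 26.0-fold, SPHK1 22.7-fold and ATP6V0D2 at least 22.2-fold. KCNG1, a potassium channel subunit, and SLC30A3 were both 21.1-fold higher. TNFRSF11B was at least 112-fold lower, PDE5A at least 64.7-fold, LRRC17 at least 47.9-fold, PDGFRA at least 37.3-fold and WNT5A, a secreted signalling protein, at least 29.4-fold. TMEM47, MAP3K20 and the adhesion molecule ALCAM were lower by 60.2-fold, 57.7-fold and 57.4-fold. In total 8780 genes passed, 4825 higher and 3955 lower, 2728 and 2735 of them by at least 2-fold. With median centring the split was 2617 and 5108 (median of all genes -0.19 against 0.15), with reference genes 1902 and 5681 (median -0.36) and 691 and 5854 in the value table (median -0.45). DKC1 was at -0.01 (adjusted p = 0.937). The lower signal and the probe disagreement on the hTERT mutant arrays enter this comparison too.

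Each of the 4 list calls below was lost with an estimated correlation (adjusted p = 0.864). Of 28 matrix genes 20 fell and 4 rose (adjusted p = 0.00012), with COL3A1 48.8-fold and COL5A2 29.2-fold lower. Of 21 contractile genes 14 fell and 3 rose (adjusted p = 0.00718), with TAGLN 8.15-fold and TPM1 6.99-fold lower. Of 24 ATF4 genes 18 rose and 4 fell (adjusted p = 0.0198), with TRIB3 19.2-fold and SESN2 9.34-fold higher and HSP90B1 8.84-fold lower. Of 29 mitosis genes 18 fell and 2 rose (adjusted p = 0.021), with TOP2A at least 3.37-fold and CCNA2 at least 3.43-fold lower. Adjusted over the list alone, 15 contractile genes fell and 3 rose, and the other 3 lists had the same numbers. fry called 19 lists. Without the hTERT 47A array the mitosis list (adjusted p = 0.0884) and the ATF4 list (adjusted p = 0.0563) no longer passed. The mitosis list was also lost without background correction (adjusted p = 0.0503), with median centring (adjusted p = 0.0874), with reference genes (adjusted p = 0.1) and in the value table (adjusted p = 0.314), with a mean below 0 in each. Among genes of lists that did not pass, HRK was at least 14.7-fold higher, GDF15 10.4-fold higher, NBN at least 8.73-fold lower, and ATM, the kinase that signals DNA breaks, at least 2.68-fold lower.

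hTERT against parental cells over all constructs compares 4 arrays with 4, with the construct as a term. CTAG2, a cancer-testis antigen, was at least 12.1-fold lower in hTERT cells (log2 difference -4.28, SE 0.18, adjusted p = 0.0125). SRGN, the proteoglycan serglycin, was 12.8-fold lower (adjusted p = 0.0241), and COX7A1, a subunit of cytochrome c oxidase, at least 6.15-fold lower (adjusted p = 0.0241). These 3 genes were the only ones past the threshold in limma as planned (2684 at an unadjusted p under 0.05). The fit assumes the same cell-type difference for every construct, so the interaction, which passed for 7202 genes, enters its residual spread. A small count here is thus no sign that the cell types are alike. With control hTER 1195 genes passed between them, and with mutant hTER 8780. With each of the 8 arrays left out in turn 0 genes passed, and without the construct term 321 did.

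Values that did not pass on the lower side were those of CCND2, cyclin D2, at -4.63 (adjusted p = 0.0851), CYP1B1, a cytochrome P450, at -4.13 and OLR1 at -4.02. On the higher side were MMP1 at 3.31 (adjusted p = 0.221), OASL at 3.08, ADGRG1 at 2.67, KCNG1 at 2.57, PLEKHO1 at 2.50 and CRMP1 at 2.32. Camera called 0 lists, with 0 also under an estimated correlation, and fry called the hypoxia and glycolysis list (adjusted p = 0.0497). Adjusted over the list alone, 5 genes of that list rose and 1 fell, against 0 over all genes. Of the other lists, 1 mitosis gene and 1 replication gene rose, and in the ATF4 and packaging lists 1 gene rose and 1 fell, when adjusted over the list alone. With median centring 2 lists passed in camera, with reference genes 7, with the authors' values 8, and with an array left out 1 to 5. The median log2 difference of all genes was 0.09 as normalized, -0.13 with median centring, and -0.29 both with reference genes and in the value table.

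hTERT against parental cells with control hTER, added after seeing the data, compares the cell types on the control arrays. Its spread comes from the fit of all 8 arrays, so the mutant arrays still enter the p-values. As lists, mitosis, replication and the interferon response were higher in hTERT cells in camera with a preset correlation, with 17 of 29, 10 of 28 and 7 of 30 genes past the threshold, but 0 of the 3 passed with an estimated correlation (adjusted p = 0.471). CDC20, an activator of the anaphase-promoting complex, was 5.19-fold higher (log2 difference 2.38, SE 0.31, adjusted p = 0.00616), and IFITM1, an interferon-induced membrane protein, 5.25-fold. CDC20 lost its call with the hTERT or the parental array of wild-type hTER left out. MXRA5, a matrix-remodelling protein, was 9.87-fold higher (log2 difference 3.30, SE 0.16, adjusted p = 6.24e-05). CCND2 was 16.2-fold lower (adjusted p = 0.00132) and CTAG2 at least 13.8-fold lower (adjusted p = 1.04e-05).

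FGL2, a secreted fibrinogen-like protein, was 7.68-fold higher, CRMP1 6.91-fold, GPC4, a glypican, 6.54-fold, ALPL, an alkaline phosphatase, 6.46-fold and FABP4, a fatty acid binding protein, 6.19-fold. LCE2A, PRRX2, GDF6 and ACKR3 were higher by 5.84-fold, 5.78-fold, 5.57-fold and 4.96-fold. SRGN was 10.6-fold lower, CYP1B1 8.66-fold and COX7A1 at least 6.87-fold. TFAP2A, a transcription factor, was also lower, as were RTN1, SCG5, NSG1, COL11A1, QPRT and HOXB8. LCE2A, COL11A1 and QPRT lost their call with at least 1 of the control arrays left out. In total 1195 genes passed, 686 higher and 509 lower, against 583 and 861 with median centring, 459 and 2138 with reference genes (median of all genes -0.23 against -0.02) and 362 and 1303 in the value table (median -0.12). Fewer passed with a control array left out: 44 without hTERT wild-type, 62 without parental wild-type, 88 without hTERT vector and 98 without parental vector. Without either hTERT mutant array 2606 passed. DKC1 was at -0.15 (adjusted p = 0.61).

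Each list call of this paragraph was lost with an estimated correlation (adjusted p = 0.471). Of 29 mitosis genes 17 rose and 0 fell, and 21 and 0 when adjusted over the list alone (camera, adjusted p = 2.86e-13). UBE2C, a ubiquitin-conjugating enzyme of mitosis, was 3.84-fold higher and KIF20A, a mitotic kinesin, 3.21-fold. In the replication list 10 of 28 rose and 0 fell, and 18 and 1 when adjusted over the list alone (adjusted p = 1.53e-08), with CDT1, a licensing factor of replication origins, 3.81-fold and TK1 3.19-fold higher. In the interferon list 7 of 30 rose and 0 fell, and 14 and 0 when adjusted over the list alone (adjusted p = 2.01e-07), with IFI6 3.74-fold and IFI27 3.30-fold higher. In the hypoxia and glycolysis list 5 of 21 rose and 0 fell, against 2 and 2 with reference genes and 5 and 1 when adjusted over the list alone (adjusted p = 0.00545), with the aldolase ALDOC 3.68-fold higher. The matrix list had 6 of 28 higher and 1 lower, and 7 and 2 when adjusted over the list alone (adjusted p = 0.00901), with BGN, the proteoglycan biglycan, and FBLN1, fibulin-1, both 2.86-fold higher. The ribosomal list had 4 of 22 higher and 0 lower, against 0 and 0 with median centring or reference genes and 5 and 0 when adjusted over the list alone (adjusted p = 0.00901). Of the 9 genes named in this paragraph each but ALDOC lost its call with at least 1 of the control arrays left out.

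The 3 lists called in the other direction were also lost with an estimated correlation (adjusted p = 0.471, and adjusted p = 0.473 for p53 targets). They were cholesterol synthesis, with 0 of 22 higher and 2 lower and 0 and 5 when adjusted over the list alone (adjusted p = 0.00901), heat shock, with 0 of 15 higher and 1 lower (adjusted p = 0.00656), and p53 targets, with 0 of 30 past the threshold (adjusted p = 0.0389). IDI1, an isomerase of isoprenoid synthesis, was 1.72-fold lower. All 9 lists kept their direction in every scaling run. fry called hypoxia and glycolysis alone of the 23. The p53 list no longer passed without hTERT wild-type (adjusted p = 0.235) or parental wild-type (adjusted p = 0.0638).

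Single constructs were described without a test. In hTERT cells 6986 genes lay at least 1.5-fold from both controls with 47A and 8040 with AU5, against 138 between wild-type hTER and vector. In parental cells the numbers were 143 with 47A, 89 with AU5 and 237 between wild-type hTER and vector. The wild-type numbers need only a single difference between arrays, which is easier to meet than distance from both controls. A larger wild-type number thus does not mean that the mutants changed fewer genes. These counts depend on the processing: without background correction the parental ones were 33, 22 and 46, and 35, 22 and 75 in the value table, where those of 47A and AU5 in hTERT cells were 3873 and 4466. With a different control array for each mutant, the changes of 47A and AU5 correlated across genes at r = 0.93 or 0.94 in hTERT cells and at r = -0.24 or -0.25 in parental cells, where genes are not independent replicates. Between the mutants, 2627 genes in hTERT cells and 778 in parental cells lay at least 1.5-fold apart. CALD1 was 84.2-fold lower with AU5 than in the nearer control in hTERT cells, and COL3A1 69.6-fold lower with 47A. In parental cells 47A gave a 2.33-fold higher CYP26B1, a 2.87-fold lower INHBE, an activin subunit, and a 2.83-fold lower HSPA6. AU5 in parental cells gave a 10.4-fold lower ACTG1, the gamma-actin gene, a 3.43-fold lower MRC2, a collagen receptor, and a 2.63-fold lower PKM, a pyruvate kinase. On this array probes of the same gene disagreed by over 1 log2 unit for 3.8% to 14.4% of genes in its 5 pairs with arrays other than the hTERT mutant ones, against 0% to 6.58% in the 10 pairs without it. A second probe for PKM read 559 with AU5 and 466 to 679 on the other parental arrays, and ACTG1 and MRC2 had 1 probe each.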

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

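The 3 tests of the breadth of change on the hTERT mutant arrays and the 2 tests of the lists in parental cells were chosen only after the results were seen. The other tests in this part were set out before.

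The test of the interaction picked out the effects that differ between hTERT and parental cells. It called 7202 genes in limma. On the log2 scale, and relative to parental cells, the effect of mutant hTER in hTERT cells was higher by 6.38 for KRTAP21-2, 6.20 for FOLR3, 6.04 for CCL26, 5.72 for MMP3, 5.60 for GCNT3 and 5.45 for KIF1A. It was higher by 5.17 for RASD1, 5.05 for SPHK1, 4.85 for ATP6V0D2, 4.84 for SLC30A3, 4.80 for OASL and 4.64 for GDF15. Among the lowest, the difference was -6.87 for TNFRSF11B, -6.81 for PDE5A, -6.64 for PDGFRA, -6.13 for THBS1, -6.11 for COL3A1 and -6.09 for BDNF. It was -5.99 for MAP3K20, -5.97 for LRRC17, -5.85 for RECK, -5.84 for NPTX1, -5.80 for CLDN11, a claudin, and -5.78 for PRRG1. Where a side was not detected these are fitted values and not bounds. The lists below passed in camera with a preset correlation, and 0 of them with an estimated one (adjusted p = 0.679 to 0.687). Their mean differences were -2.42 for the matrix, -1.64 for mitosis, -1.50 for contractile genes, -1.04 for interferon and -0.74 for replication, and 1.20 for the ATF4 response and 1.07 for serum and immediate early genes.

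The 8664 genes called in hTERT cells rest on 2 arrays with mutant hTER, which also had fewer probes detected. On log2 signals with no normalization 6976 genes still passed, 5833 lower and 1143 higher. An even loss of signal would itself give lower genes there, so only the higher ones bear on it. Of these, 268 were at least 2-fold higher, so normalization or an even loss of signal is not the whole cause. Probes of the same gene disagreed by over 1 log2 unit for 24.2% of genes against 5.13% among the other arrays, as RNA degradation or another uneven loss along transcripts would give. Larger changes of any cause could also raise this share, because the cut is fixed. The median absolute log2 change with mutant hTER was 0.86 in hTERT cells and 0.09 in parental cells, so the share alone does not single out such a loss. The interaction passed for 82.7% of the genes called in hTERT cells, but with 0 genes called in parental cells any cause on these 2 arrays would give a high share, so this does not decide whether mutant hTER acts together with hTERT. Both explanations stay open and may hold together, because both belong to the same 2 arrays.

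Longer genes fell more on the hTERT mutant arrays: Spearman's rho between log2 change and genomic length (GRCh38) was -0.33 across 11877 genes, 96.5% of those tested, and the median change went from 0.62 in the shortest decile to -0.48 in the longest. Brightness does not account for this, since rho was -0.21 or lower in each of 5 classes of brightness on the control arrays. Other arrays also had a trend with length, weaker and in the other direction. In parental cells rho was 0.10 with 47A and 0.09 with AU5. Between wild-type hTER and vector it was 0.12 in hTERT cells and 0.14 in parental cells. RNA degradation that strikes long genes more could not be decided: probe disagreement rose with length at rho = 0.16 (95% bootstrap interval 0.058 to 0.262, 387 genes), an interval that spans the bound of 0.1 set before, and genes are not independent replicates. Among 205 genes whose probes agreed within 0.5 log2 unit, rho between change and length was -0.097 (95% bootstrap interval -0.227 to 0.032). It was -0.27 over 6725 genes with a detection p-value under 0.01 on all 8 arrays. A weaker trend where probes agree is what an uneven loss would give. However, rho was not computed for the genes whose probes disagreed, and most genes of the wider sets had a single probe. A trend that weakens with probe agreement is thus not shown. Genes with agreeing probes may also have changed less, which was not tested, so the question stays open. No biological explanation of the length trend was tested.

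The ATF4, heat shock, immediate early and senescence lists passed as lower for mutant against control hTER in parental cells. Without the parental 47A array 0 of these 4 lists passed, and their medians as normalized by quantiles were -0.22, -0.34, -0.22 and -0.21 with 47A but -0.036, 0.015, -0.064 and -0.029 with AU5, so the 47A array may carry the calls alone. With an estimated correlation among the genes of a list 0 of the 4 passed, as correlated genes within a list would give. The estimates were 0.22, 0.29, 0.18 and 0.12 in the same order, above the preset 0.01, so the p-values at the preset correlation may be too small. The test with an estimated correlation also raised p for lists with an estimate below 0.01. The loss of the calls alone thus cannot tell whether correlation was the reason. An effect of 47A in parental cells stays open, because it was on 1 array there.

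For hTERT against parental cells over all constructs, 3 of 32 splits of the 8 arrays that allow a fit with construct gave at least 3 genes, the real split included. The other 2 gave 7556 each, which points to a structure of the arrays: they part only the pairs with 47A and with AU5, so with the construct term they repeat hTERT against parental cells with mutant hTER and do not measure chance. Among the 8 splits that part all 4 pairs of arrays with the same construct, too few for a share under 0.05, the real split gave 3 genes and the highest other 0.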

How the results depend on the processing

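The comparison with control hTER, the scaling on reference genes, and median centring of the gene lists were chosen only after the data were seen. Every alternative set out before the data were examined gave a value. The cause of the differences below was not tested except where stated. Signal over background limits genes near the detection level, which have only bounds.

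Counted below are named genes that kept direction and call in every setting that measured them. Lists counted did so in every setting with a preset correlation, and 0 passed with an estimated one. For mutant against control hTER in hTERT cells this held for 97 of 108 named genes and 4 of 6 lists. For the interaction this held for 85 of 105 genes and 4 of 7 lists, for hTERT against parental cells with mutant hTER for 91 of 109 genes and 2 of 4 lists, over all constructs for 0 of 3 genes, and with control hTER for 22 of 67 genes and 8 of 9 lists. With an array left out the counts ranged from 7167 to 9356 genes in hTERT cells, from 0 to 0 in parental cells, from 5628 to 8542 for the interaction, from 7835 to 9433 with mutant hTER, from 0 to 0 over all constructs, and from 44 to 2606 with control hTER. The lists called ranged from 4 to 8, 0 to 8, 5 to 9, 2 to 4, 1 to 5 and 8 to 11 in the same order.

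With genes detected on all 8 arrays, 5296 of 6929 genes passed in hTERT cells, 4451 for the interaction, 5347 with mutant hTER, and 0 over all constructs, and here fewer genes were tested. Over all constructs 1 gene passed without background correction, 6 without a filter, 1 with a trended and robust variance, 5 with reference genes, and 321 (201 higher, 120 lower) without the construct term. With control hTER 2597 genes passed with reference genes.

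With an estimated correlation 0 lists passed in hTERT cells, in parental cells, for the interaction, with mutant hTER and with control hTER. fry called 18 lists in hTERT cells, 0 in parental cells, 16 for the interaction, 19 with mutant hTER, 1 over all constructs and 1 with control hTER. The value table gave 11 lists in hTERT cells, 8 in parental cells and 8 over all constructs. Median centring gave 8 in parental cells and 2 over all constructs, and reference genes gave 8 in parental cells, 8 with mutant hTER and 7 over all constructs.

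At 2-fold in place of 1.5-fold, single-construct counts were 4315 for 47A and 5586 for AU5 in hTERT cells, 12 and 16 in parental cells, and 10 and 21 for wild-type hTER over vector in hTERT and parental cells, a stricter limit by construction. In this paragraph too, the wild-type counts need only a single difference and the mutant counts distance from both controls. Without background correction they were 33 and 22 for 47A and AU5 in parental cells, 26 for wild-type hTER in hTERT and 46 in parental cells. The value table gave 3873 for 47A and 4466 for AU5 in hTERT cells, 35 and 22 in parental cells, and 90 and 75 for wild-type hTER.

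Among named genes that had passed as normalized, directions turned for 17 values. Sign changes of genes and lists that had not passed are not in this count. For named genes in parental cells, where 0 genes passed, 44 values changed sign and 1747 did not. INA, a neuronal intermediate filament gene, went from 0.49 to -0.062 (median centring), -0.43 (value table) and -0.035 (reference genes) in hTERT cells, and for the interaction from 0.53 to -0.088, -0.45 and -0.098. CDKN2A, an inhibitor of the cell cycle, went from 0.49 to -0.48, -0.41 and -0.64 with mutant hTER. CD14 turned to -0.38 (value table) and -0.12 (reference genes) there. In the value table alone FDPS turned to -0.023 and TBP to -0.013 for the interaction, and FEN1 to -0.17, MCM5 to -0.21, SV2A to -0.025 and TBP to -0.17 with mutant hTER.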

Other observations

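The first 2 paragraphs describe values with no test. The counts with gene length in the last paragraph were computed after the length trend was seen.

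Between wild-type hTER and vector, the mitosis and interferon lists differed in opposite directions in the 2 cell types under every scaling, and the replication list under every scaling but the authors' value table. In hTERT cells the median of the mitosis list, which holds genes of the spindle and chromosome segregation, was 0.54 higher on the log2 scale with wild-type hTER than with vector, above all of 10000 random lists (percentile 100). The replication list was 0.25 higher, but at -0.063 in the authors' value table, where the median over all genes was -0.23. The interferon list was at -0.42 and the senescence list at -0.24, both at percentile 0. In parental cells mitosis was at -0.38 and replication at -0.28, while interferon was at 0.20 and the NRF2 list, genes of the oxidative stress response, at 0.26. The senescence list was at -0.080 there, in the same direction as in hTERT cells. The other medians of this paragraph kept their direction under every scaling. These are differences between 2 arrays of each cell type. The estimated correlation among mitosis genes was 0.67 in the class fit, and random lists are not matched on this. An extreme percentile can therefore arise from a small difference between arrays.

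In parental cells, with 47A the contractile list had a median of 0.36, cholesterol synthesis 0.23 and the matrix list 0.20, each above all random lists and higher under every scaling. Here too the random lists were not matched on correlation among genes. COL3A1 was 1.79-fold above the nearer control and KRTAP1-5 1.88-fold. Below the nearer control were BIRC3, an inhibitor of apoptosis, by 2.32-fold, HMOX1 by 2.21-fold, AKR1B1, an aldose reductase, by 2.14-fold and FOS by 2.07-fold. With AU5 the genes farthest below the controls included ALYREF, an adaptor of mRNA export, by 2.60-fold, TUBB6, a tubulin, by 2.54-fold and PSMC4, a proteasome subunit, by 2.32-fold. A probe for ACTB read 6943 on that array and 15403 to 20138 on the other 3 parental arrays, while another ACTB probe read 22061 there and 23663 to 24509 on the others.

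Of the genes in the shortest decile of length, 55.8% were higher and 12.5% lower with mutant hTER in hTERT cells, and in the longest decile 19.7% and 49.7%.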
